A study of Canis lupus familiaris with 30 samples.

How the data were processed

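Total RNA of peripheral blood mononuclear cells from dogs on 2 diets was compared on 30 Agilent 2-colour arrays. Per the labels the cells came from density centrifugation, 200 ng of RNA was amplified and labelled, and each sample was one of 6 biological replicates of a group of diet and week. Per the file headers each array was scanned and read with Agilent Feature Extraction 10.10.1.1. Per the file headers the scanner files give the median intensity of each spot in Cy3 and Cy5 with its local background in arbitrary fluorescence units, and the deposited matrix gives 1 normalised log2 ratio per probe and array, made by the authors with limma. The deposited ratios correlated with those computed here at 0.856 to 0.995 per array.

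The scanner files were read anew. Of 45220 spots per array 43803 were not controls, and these held 43603 probes, 2175 of them with a gene symbol. Over all arrays 979 spots that Feature Extraction had marked as faulty were left out, and 0 spots were saturated. Background was corrected by normexp with an offset of 50 on the median signal. The plan named the mean signal, which the files do not hold. The log2 ratios of Cy5 over Cy3 were normalised by loess within each array. Probes well above background in at least 7 of the 60 channels were kept (31691), and each gene or accession was represented by its brightest probe, giving 25950 units, 1087 of them with a symbol.

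Between 20085 and 42703 probes in Cy3 and between 19416 and 43411 in Cy5 stood well above background, and the number of arrays limits the precision.

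The log ratios were fitted with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with a term for each group and a gene-specific dye term, which leaves 23 residual degrees of freedom. No array joins weeks 0 and 9 to weeks 3 and 6, so the arrays form 2 loops, and 12 comparisons can be made within them. Time arrays have 1 dye order per diet, so the mean of the arrays alone contains the dye effect there, and fitted values were used. The dye term passed in 5615 units (21.6%), with a median size of 0.049 log2. Tests were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Changes between the loops came from a separate-channel limma fit (lmscFit) of quantile-normalised A values on the 25536 units with no missing value, where week pair and slide cannot be told apart.

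For gene groups 31 lists were fixed in advance and 18 had at least 5 measured members. These 18 were tested in the 12 comparisons with camera at a preset correlation of 0.01, adjusted over 216 tests, with camera at an estimated correlation and fry beside it. Missing values were filled with fitted values for these tests. Members were also adjusted over the list alone.

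Genes were named by a rule. For the changes from week 0 to 9, the diet difference at week 9, its mean over weeks 3, 6 and 9 and the interaction at week 9, the rule takes the 10 passing named genes with the largest absolute log2 value in each direction, and 3 for the other comparisons. Where fewer than 5 pass, it takes those and the 3 with the smallest p in each direction. Up to 4 members with the smallest p of each list with a passing test, or with members passing over the list alone, were added.

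Alternatives were no background correction, the Feature Extraction processed signals, the deposited values, median centring, scaling between arrays, no filter and a filter of 30 channels, no dye term, the slide as a fixed or random block, the replicate number as a block, moderation with trend and robust, array weights, the arrays of the loop alone, the arrays of the 2 groups alone, the mean over a gene's probes, and leaving out each array. A dye term per scan session, leaving out each slide of the time arrays or the first 2 arrays of slide 1, and the list tests under median centring, scaling and without single slides were added after the data were seen. On simulated data with 100 changed genes of each size, between 62 and 96 of 100 changes of 0.5 log2 and between 92 and 99 of 100 changes of 1 were recovered per comparison.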

Results

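Gene expression was measured in peripheral blood mononuclear cells (PBMC), the white cell fraction of blood recovered by density centrifugation, from adult dogs. The dogs ate 1 of 2 diets for 9 weeks: a kibble that contains carbohydrate, or raw red meat rich in protein and fat. Per the labels 8 dogs ate kibble and 7 ate meat, and blood was taken at the start (week 0) and at weeks 3, 6 and 9, which gives 8 groups of diet and week. The samples were labelled with Cy3 or Cy5 and compared in pairs on 30 arrays. Of these, 16 set weeks against each other within a diet, 4 for each of weeks 0 against 9 and 3 against 6 on each diet. The other 14 set meat against kibble within a week, 3 at week 0, 3 at week 3, 4 at week 6 and 4 at week 9. The diet arrays of each week lay on a slide of their own, so on them week and slide cannot be told apart. At weeks 0 and 3 their dye orders were 2 arrays against 1. Each group was read in 7 or 8 channels, while the labels state 6 biological replicates per group. If so, some samples were read more than once within a group, yet the fit treats the arrays as independent. Which dog is on which array is not given and the same dogs were sampled at every week, so the p-values measure the spread between arrays, not between dogs. Between 20085 and 42703 probes per array stood well above background in Cy3 and between 19416 and 43411 in Cy5. The number of arrays limits the precision of every value. A test covered 25950 genes and unnamed transcripts, of which 1087 carried a gene symbol. Named genes and gene groups come from those 1087, and counts of genes refer to all 25950.

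**Figure D1:**
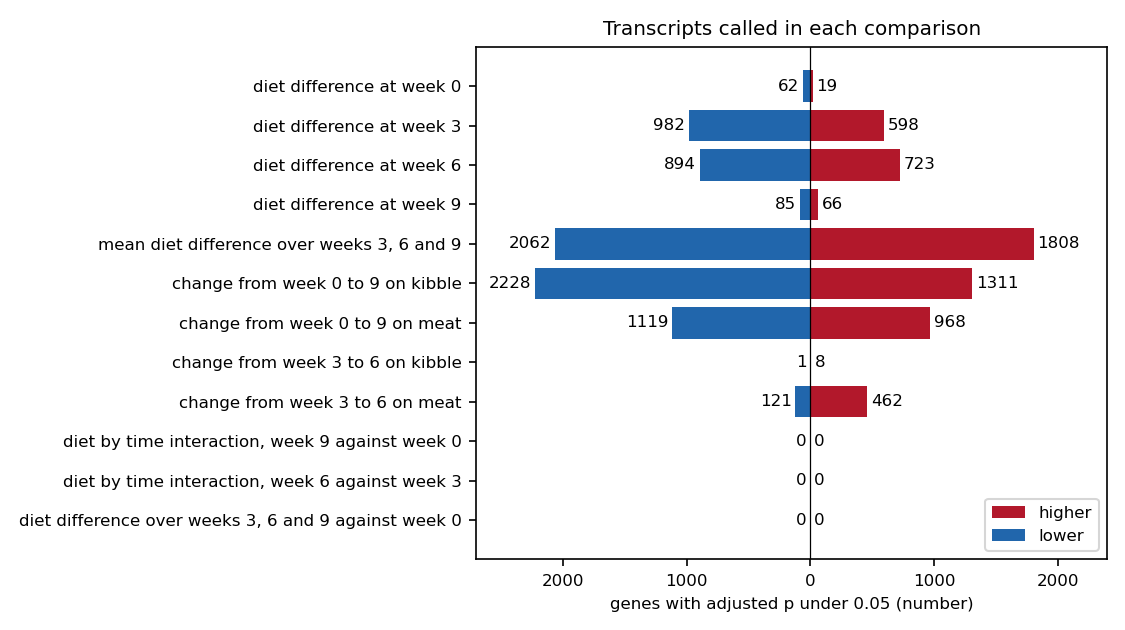
Number of genes and unnamed transcripts with an adjusted p under 0.05 in limma in each of the 12 comparisons, with bars to the right for higher (in meat-fed dogs, or at the later week) and to the left for lower. The mean diet difference has the most genes, 1808 higher and 2062 lower, the change from week 0 to 9 on kibble has the most lower genes, 2228, and the 3 tests of whether a difference changed between weeks have none.

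The first question was how the PBMC of meat-fed dogs differed from those of kibble-fed dogs while the diets were fed, as a mean over weeks 3, 6 and 9. The largest differences among named genes were lower transcripts in the meat-fed dogs. CAMP, a peptide antibiotic stored in neutrophil granules, was 5.8-fold lower (log2 -2.54 ± 0.29 SE, lower on 11 of 11 arrays, adjusted p = 3.93e-06). MS4A2, a chain of the IgE receptor of basophils and mast cells, was 2.26-fold lower (log2 -1.17 ± 0.11, 11 of 11 arrays, adjusted p = 2.97e-07). The MS4A2 difference was of the same size at week 0 (log2 -1.17 ± 0.18), so it was not particular to the fed weeks. GP1BA, part of the platelet receptor for von Willebrand factor, was 2.47-fold lower (log2 -1.31 ± 0.18, 11 of 11 arrays, adjusted p = 3.73e-05). PTGS1, the cyclooxygenase of platelets, followed at log2 -1.19 ± 0.19 and AK1, an adenylate kinase, at -1.04 ± 0.13, each lower on 11 of 11 arrays. TSHB (-0.99), HSD17B14 (-0.98), CCL5 (-0.92), SVIP (-0.91) and ITGA2B (-0.90) complete the 10 largest. Transcripts higher in meat-fed dogs differed by less. CD1A6, a CD1 molecule that presents lipid antigens, was 1.61-fold higher (log2 0.69 ± 0.17, 10 of 11 arrays, adjusted p = 0.0068), and CCR9, a receptor that guides lymphocytes to the gut, was 1.34-fold higher (log2 0.42 ± 0.12, 8 of 11 arrays, adjusted p = 0.0177). TYMS, which makes thymidylate for DNA synthesis, was higher by log2 0.38 ± 0.08, and the lactate dehydrogenase LDHB by 0.37 ± 0.08. ADH5 (0.39), FHIT (0.35), LTB (0.34), KCNA2 (0.34), CD40LG (0.33) and the glucose transporter SLC2A1 (0.33) also passed. Median centring ended the limma calls of LDHB (adjusted p = 0.0689) and LTB (adjusted p = 0.0978), among others.

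Taken by groups, markers of several blood cell types were lower in the meat-fed dogs over weeks 3, 6 and 9. Of 7 platelet markers 5 were lower, among them the fibrinogen receptor chains ITGA2B (log2 -0.90 ± 0.18) and ITGB3 (-0.74 ± 0.14) and clusterin, CLU (-0.79 ± 0.10). Of 6 monocyte markers 4 were lower: CYBB, the catalytic chain of the phagocyte oxidase (-0.69 ± 0.10, lower on 10 of 11 arrays), the haemoglobin receptor CD163 (-0.60 ± 0.14), the endotoxin receptor TLR4 (-0.43 ± 0.10) and the protease CTSS (-0.39 ± 0.09). Of 8 cytotoxic T and NK cell markers 5 were lower, including CCL5 (-0.92 ± 0.15), the chemokine receptor CX3CR1 (-0.52 ± 0.10), CD8A (-0.45 ± 0.11) and perforin, PRF1 (-0.31 ± 0.10). That difference lay at weeks 3 and 6 (list means of -0.56 and -0.54), though each week's diet arrays had their own slide. At week 9 5 of 8 cytotoxic markers were positive (list mean 0.04, set test adjusted p = 0.507) and 0 were called in limma by either adjustment. Of 7 neutrophil markers 3 were lower: CAMP, lactoferrin (LTF, -0.77 ± 0.16) and neutrophil elastase (ELANE, -0.15 ± 0.04). Adjusted over the list alone, the counts were 5 of 7, 4 of 6, 6 of 8 and 3 of 7. The set test passed for each: adjusted p = 0.00213 for platelet, 0.0084 for monocyte, 0.0179 for cytotoxic and 0.043 for neutrophil markers. With an estimated correlation between genes in place of the preset one, the adjusted p = 0.738 for each of these 4 lists. Fry, which asks only whether a list's genes move one way, gave adjusted p = 0.000334, 0.00333, 0.00333 and 0.00733 in the same order. Ribosomal protein genes went the other way by small amounts, 4 higher and 1 lower of 18. RPS27A was higher by log2 0.31 ± 0.05 and RPSA by 0.17 ± 0.05, while RPL18 was lower (-0.25 ± 0.07). This rested on week 6 (list mean 0.17), as the list means were 0.01 at week 3 (adjusted p = 0.442) and -0.02 at week 9 (8 of 18 positive, adjusted p = 0.65). Here too the diet arrays do not tell the week apart from its slide. That list passed at adjusted p = 0.019, against adjusted p = 0.776 with an estimated correlation and 0.279 by fry. Scaling the arrays to one spread ended the set calls of the ribosomal (adjusted p = 0.129) and neutrophil lists (adjusted p = 0.0749), and no list changed direction under either other normalisation. Among single genes, median centring ended the limma calls of TLR4 (adjusted p = 0.0941), CTSS (0.186), CD8A (0.13), RPS27A (0.0838) and RPSA (0.297), among others.

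Lists of metabolic genes did not pass the set test over weeks 3, 6 and 9, although single members did. CPT1A, which admits fatty acids to mitochondria for oxidation, was lower in meat-fed dogs (log2 -0.36 ± 0.07, 9 of 11 arrays, adjusted p = 0.00166), and so was catalase, CAT (-0.35 ± 0.08, 8 of 11 arrays, adjusted p = 0.00252). They were the 2 genes called of 5 measured in the list of fatty acid oxidation genes and PPAR targets. It was 3 when adjusted over the list alone, with a list adjusted p = 0.336. Median centring ended the limma calls of CPT1A (-0.29, adjusted p = 0.101) and CAT (-0.27, adjusted p = 0.107). In glycolysis LDHB and SLC2A1 were higher and GAPDH lower (-0.24 ± 0.08), 3 of 5 genes by either adjustment, with a list adjusted p = 0.354. The GAPDH call was lost in 25 of 47 alternative fits, those without 1 array included (adjusted p up to 0.456). Of 7 oxidative stress genes the ferritin chain FTH1 (-0.58 ± 0.13) and haem oxygenase HMOX1 (-0.25 ± 0.08) were lower and SOD1 higher (0.17 ± 0.05), 1 higher and 5 lower when adjusted over the list alone (list adjusted p = 0.385). FTH1 and HMOX1, with CD163, were also the 3 lower genes of 7 in the iron and haem list, 4 when adjusted over the list alone (list adjusted p = 0.242). Fry passed for these 4 lists at adjusted p = 0.0155, 0.0254, 0.0239 and 0.0209. Among 14 T cell activation genes ICOS (0.19 ± 0.04) and TNFRSF18 (0.15 ± 0.05) joined CD40LG as higher and the IL-2 receptor chain IL2RA was lower (-0.40 ± 0.09), the same 4 when adjusted over the list alone (list adjusted p = 0.169). The co-stimulatory receptor CD28, in a list too small to test, was higher by 0.25 ± 0.05. Genes of antigen presentation by MHC class II held 3 lower of 11, DLA-DQA1 (-0.25), CD80 (-0.29) and CTSS, or 4 adjusted over the list alone (list adjusted p = 0.179). This list is called MHC class II genes below, though it also holds co-stimulatory ligands such as CD80 and proteases such as CTSS. Of 4 heat shock genes HSPB1 (-0.41 ± 0.06) and HSP70 (-0.24 ± 0.07) were lower, while HSPA4 (0.02) and DNAJA1 (0.08) did not pass. Annexin A1 (ANXA1, -0.32 ± 0.08) and the mitochondrial arginase ARG2 (-0.41 ± 0.13) were lower, and these lists too had too few measured genes to test.

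Over all genes 1808 were higher and 2062 lower in meat-fed dogs (adjusted p under 0.05 in limma), 3870 of 25950, of which 76 and 163 had a symbol. Where a called named gene had more than 1 probe, 157 of 165 other probes (95.2%) pointed the same way, against 82 of 98 (83.7%) for week 0 to 9 on kibble and 64 of 70 (91.4%) on meat. The median ratio of the other probes' values to that of the reported probe was 0.81, 0.57 and 0.65 in the same order. The balance of higher and lower was 2068 and 1892 with Feature Extraction signals. Median centring in place of loess left 1080 calls, 540 each way, and the 11 diet arrays of these weeks alone gave 2388. Of the 49 called genes that the naming rule picked here and that were run in the alternatives, 19 kept their call in each alternative and each fit without 1 array, among them CAMP, MS4A2, GP1BA, CYBB, CLU, CCL5 and LTF.

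**Figure D2:**
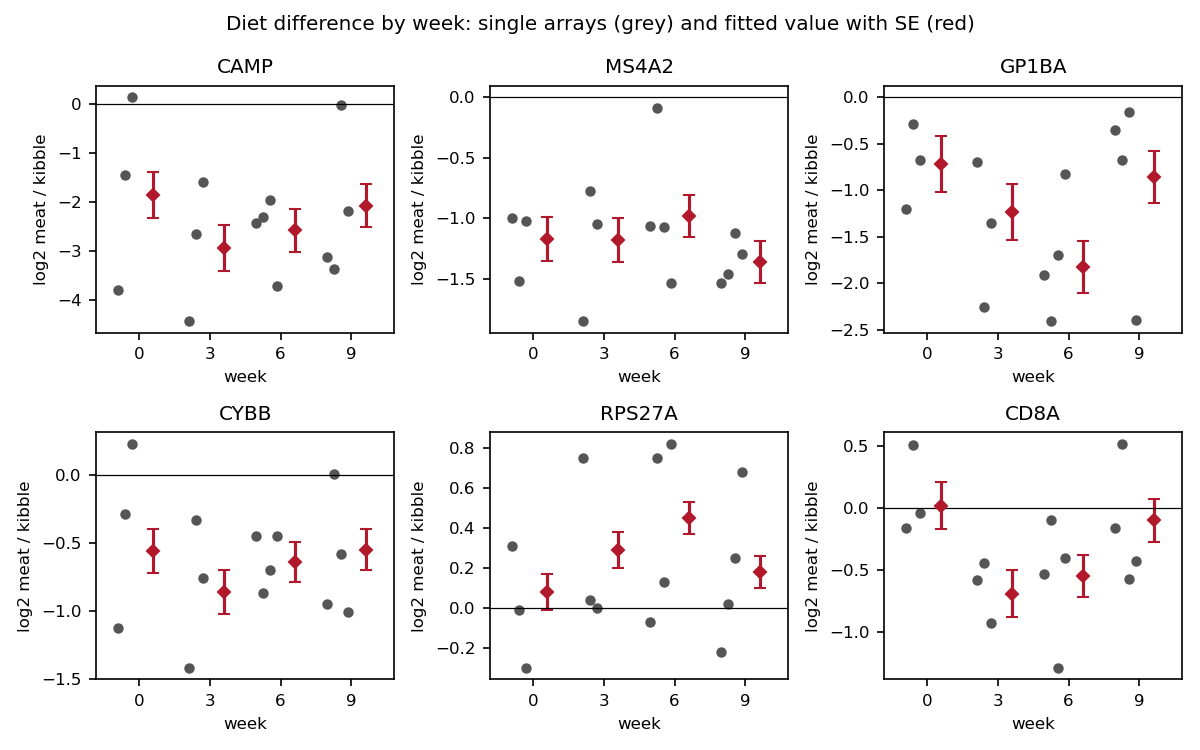
Log2 ratio of meat over kibble by week for CAMP, MS4A2, GP1BA, CYBB, RPS27A and CD8A; grey points are single arrays (3 at week 0, 3 at week 3, 4 at week 6, 4 at week 9) and red diamonds the fitted values with SE. CAMP lies below 0 on all 11 arrays of weeks 3, 6 and 9, with fitted values between -2.95 and -2.08, and MS4A2 lies below 0 at week 0 as well (fitted value -1.17).

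At week 3 several monocyte, cytotoxic and MHC class II genes were lower in the meat-fed dogs, though with an estimated correlation none of these lists passed (adjusted p = 0.738 for each). CAMP was 7.74-fold lower in the meat-fed dogs (log2 -2.95 ± 0.47, 3 of 3 arrays, adjusted p = 0.00115), CCL5 2.46-fold lower (-1.30 ± 0.25, 3 of 3 arrays, adjusted p = 0.00443) and GP1BA 2.34-fold lower (-1.23 ± 0.30, 3 of 3 arrays, adjusted p = 0.0166). Of 6 monocyte markers 4 were lower, CYBB (-0.86 ± 0.16), CD163 (-0.81 ± 0.24), TLR4 (-0.70 ± 0.16) and CTSS (-0.54 ± 0.15), and 6 of 6 when adjusted over the list alone. Of 8 cytotoxic markers 3 were lower, CCL5, CX3CR1 (-0.89 ± 0.17) and CD8A (-0.69 ± 0.19), and 5 when adjusted over the list alone. Of 11 MHC class II genes DLA-DQA1 (-0.45 ± 0.12) and CTSS were lower, and 6 when adjusted over the list alone. Set tests passed at adjusted p = 0.00319, 0.00367 and 0.0214 for these lists, and the adjusted p = 0.738 for each with an estimated correlation. The MHC class II call was also lost with the slide as a block (adjusted p = 0.0797), with median centring (adjusted p = 0.057) and by fry (adjusted p = 0.0732). Platelet markers, with GP1BA and CLU (-0.87 ± 0.17) lower, and neutrophil markers, with CAMP, LTF (-1.17 ± 0.27) and ELANE (-0.25 ± 0.07) lower, did not pass the set test at week 3 (adjusted p = 0.0915 and 0.063). Adjusted over the list alone, 4 of 7 platelet and 3 of 7 neutrophil markers were lower. MS4A2 (-1.18 ± 0.18), CPT1A (-0.51 ± 0.12), CAT (-0.48 ± 0.13) and the thioredoxin reductase TXNRD1 (-0.28 ± 0.08) were lower as well. The 3 largest increases were in CYP3A12 (0.62 ± 0.18), a drug-metabolising enzyme, PSEN2 (0.50 ± 0.14) and CENPS (0.49 ± 0.14), the first 2 of which were higher on 2 of 3 arrays. In all, 598 genes were higher and 982 lower, with 5670 at an unadjusted p under 0.05. Without meat 3/kibble 3 replicate 2 (arrays are named by their Cy3 and then their Cy5 sample) 215 were called and without kibble 3/meat 3 replicate 1 587. Median centring left 127, and the 3 week 3 diet arrays alone gave 0 in limma.

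At week 6 several ribosomal protein genes were higher in meat-fed dogs and several platelet and cytotoxic markers lower, though with an estimated correlation none of these lists passed (adjusted p = 0.738 for each). Of 18 ribosomal genes 7 were higher, or 12 higher and 1 lower when adjusted over the list alone, with RPS27A at log2 0.45 ± 0.08 (3 of 4 arrays, adjusted p = 0.00305), RPSA at 0.33 ± 0.07, RPL10A at 0.27 ± 0.07 and RPL3 at 0.24 ± 0.06. Of 7 platelet markers 5 were lower by either adjustment, with GP1BA 3.56-fold lower (-1.83 ± 0.28, 4 of 4 arrays, adjusted p = 0.00112), ITGA2B 2.61-fold lower (-1.38 ± 0.28, 4 of 4 arrays, adjusted p = 0.00489) and P-selectin, SELP, 2.39-fold lower (-1.26 ± 0.25, 4 of 4 arrays, adjusted p = 0.00517). Of 8 cytotoxic markers 4 were lower, or 7 when adjusted over the list alone: CCL5 (-1.27 ± 0.24), the NK receptor KLRD1 (-0.68 ± 0.18), PRF1 (-0.61 ± 0.15) and Fas ligand, FASLG (-0.43 ± 0.13). The set tests passed at adjusted p = 8.34e-09 for ribosomal, 0.000217 for platelet and 0.00128 for cytotoxic genes, with adjusted p = 0.738 for each under an estimated correlation and 0.0185, 0.000577 and 0.00333 by fry. CAMP was 5.99-fold lower (-2.58 ± 0.44, 4 of 4 arrays), MS4A2 1.97-fold (-0.98 ± 0.17) and LOC609402, an unnamed protein-coding gene, 5.87-fold (-2.55 ± 0.64, 4 of 4 arrays, adjusted p = 0.0174). CYBB (-0.64 ± 0.15), CLU (-0.85 ± 0.15), CAT (-0.47 ± 0.12), IL2RA (-0.62 ± 0.13) and the chemokine CCL4 (-0.58 ± 0.14) were lower too. Higher transcripts included CCR9 (0.62 ± 0.18), TYMS (0.46 ± 0.12), the lysosomal phospholipase PLA2G15 (0.46 ± 0.10), LDHB (0.45 ± 0.12) and SLC2A1 (0.41 ± 0.12). In all, 723 genes were higher and 894 lower, a balance that turned with median centring (191 and 167) and array weights (1687 and 1464). The count fell to 138 without kibble 6/meat 6 replicate 1, the array on which PLA2G15 stood at 1.09 against 0.18 to 0.33 on the others, and to 950 without replicate 2 of the same kind. It was 358 with median centring, 463 with the slide as a block and 1 on the 4 week 6 diet arrays alone.

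At week 9, after the full feeding period, 10 named genes were called. MS4A2 was 2.57-fold lower in the meat-fed dogs (log2 -1.36 ± 0.17, 4 of 4 arrays, adjusted p = 0.00014) and CAMP 4.22-fold lower (-2.08 ± 0.44, 4 of 4 arrays, adjusted p = 0.0235). On kibble 9/meat 9 replicate 1 CAMP was only at -0.02, and its limma call was lost in 7 of 48 alternative fits (adjusted p up to 0.602). The heparan sulfatase SULF2 (-0.72 ± 0.15), CLU (-0.66 ± 0.15), the small heat shock protein HSPB1 (-0.60 ± 0.10) and the calcium pump ATP2B1 (-0.56 ± 0.11) were lower on 4 of 4 arrays each. The drug efflux pump ABCB1 (0.50 ± 0.10, adjusted p = 0.015) and the adenylate kinase AK6 (0.31 ± 0.07) were higher on 4 of 4 arrays each. The call of AK6 was lost in 27 of 48 alternative fits (adjusted p up to 0.692) and that of CLU in 29 of 48 (adjusted p up to 0.739). Median centring ended the HSPB1 call (-0.41, adjusted p = 0.564), as did the 4 week 9 diet arrays alone (adjusted p = 0.611), which also ended that of MS4A2 (adjusted p = 0.0915). Of 7 platelet markers 1 was lower, CLU, or 3 when adjusted over the list alone, and the list passed its set test (adjusted p = 0.00428, and adjusted p = 0.738 with an estimated correlation). CAMP was the 1 lower gene of 7 neutrophil markers by either adjustment (set adjusted p = 0.0334). Among 6 monocyte markers 0 passed over all genes in limma and 1 when adjusted over the list alone (set adjusted p = 0.0283), with CYBB at -0.55 ± 0.15 (adjusted p = 0.103). Inflammatory NF-kB targets, 0 of 14 called by either adjustment, lay to the higher side with ICAM1 at 0.21 ± 0.08 and CXCL10 at 0.26 ± 0.11 (set adjusted p = 0.0401). For each of these 4 lists the adjusted p = 0.738 with an estimated correlation, and fry gave adjusted p = 0.0548, 0.152, 0.167 and 0.201. Median centring ended the monocyte call (adjusted p = 0.105), scaling the neutrophil call (adjusted p = 0.0566) and the slide block the NF-kB call (adjusted p = 0.125). In all, 66 genes were higher and 85 lower, against 2721 at an unadjusted p under 0.05. Median centring left 10 calls, the fit without kibble 9/meat 9 replicate 2 gave 42 and that without meat 9/kibble 9 replicate 1 gave 53.

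Week 0 was compared to see how the groups stood at the start of feeding. MS4A2 was already 2.26-fold lower in the dogs of the meat group (log2 -1.17 ± 0.18, 3 of 3 arrays, adjusted p = 0.00265). SULF2 (-0.84 ± 0.16), HSPB1 (-0.63 ± 0.10) and ELANE (-0.31 ± 0.07) were lower too, each on 3 of 3 arrays, with adjusted p = 0.0204, 0.00623 and 0.0462, although ELANE lost its call in 34 of 48 alternative fits (adjusted p up to 0.945). Scaling between arrays ended the calls of MS4A2 (adjusted p = 0.0944) and HSPB1 (adjusted p = 0.0524), as did the 3 week 0 diet arrays alone (adjusted p = 0.787 and 0.889). CAMP had a log2 difference of -1.86 ± 0.47 that did not pass (2 of 3 arrays lower, adjusted p = 0.0988). In all, 19 genes were higher and 62 lower, with 2306 at an unadjusted p under 0.05. At the start 4 lists passed the set test at the preset correlation, though none did with an estimated one. MHC class II genes (10 of 11 negative, DLA-DMA at -0.30 and CTSS at -0.36, adjusted p = 0.0115), ribosomal protein genes (16 of 18 negative, RPL18 at -0.37 and RPLP0 at -0.21, adjusted p = 0.0084) and platelet markers (6 of 7 negative, GP1BA at -0.72, adjusted p = 0.029) lay to the lower side. Interferon-stimulated genes (6 of 6 positive, OASL at 0.28, MX1 at 0.69, adjusted p = 0.0135) lay to the higher side. None of these lists had a member called over all genes in limma, and adjusted over the list alone 2 MHC class II and 3 ribosomal genes were lower and 0 of the others. With an estimated correlation the adjusted p = 0.738 for each, and fry gave adjusted p = 0.199, 0.214, 0.105 and 0.348. With the slide as a block the platelet (adjusted p = 0.14) and interferon calls (adjusted p = 0.0791) ended, and scaling ended the ribosomal (adjusted p = 0.0607) and platelet calls (adjusted p = 0.168). The count rested on single arrays. It was 23 without kibble 0/meat 0 replicate 1, 51 without meat 0/kibble 0 replicate 1 and 218 without meat 0/kibble 0 replicate 2.

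The test of whether the diet difference over weeks 3, 6 and 9 departed from that at week 0 passed for 0 genes in limma (lowest adjusted p = 0.207, 2346 at an unadjusted p under 0.05). The 6 named genes with the smallest p were MED7 (log2 0.26 ± 0.06), CLNS1A (0.25 ± 0.06), RPL3 (0.26 ± 0.07), ZACN (-0.21 ± 0.06), QKI (-0.30 ± 0.10) and CD44 (-0.46 ± 0.15), with adjusted p between 0.251 and 0.365. Over all genes the diet differences of the fed weeks and of week 0 were alike: of the 3870 genes called over weeks 3, 6 and 9, 3136 (81%) had the same sign at week 0, and the correlation across genes was 0.598, against 0.15 for fits of the same design to simulated noise. Genes are not independent replicates. The list tests of this difference passed for ribosomal genes (18 of 18 positive, mean log2 0.15, adjusted p = 6.84e-09), interferon-stimulated genes (6 of 6 negative, MX1 at -1.21 ± 0.55, adjusted p = 0.00161), cytotoxic markers (8 of 8 negative, CD8A at -0.47 ± 0.21, adjusted p = 0.0214) and dendritic cell markers (5 of 5 positive, FCER1A at 0.50 ± 0.24, adjusted p = 0.04). No member passed over all genes, and adjusted over the list alone 4 ribosomal genes did and 0 of the others. The adjusted p = 0.738 for each of the 4 with an estimated correlation, and fry gave 0.0747, 0.138, 0.199 and 0.111. Leaving out meat 0/kibble 0 replicate 1 raised the count of single genes from 0 to 237. The week 0 diet arrays lay on a slide of their own, so on the diet arrays this difference cannot be told apart from the slide.

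The change over 9 weeks was asked within each diet. In the kibble-fed dogs LOC609402, an unnamed protein-coding gene, fell 15.2-fold from week 0 to week 9 (log2 -3.93 ± 0.64, 4 of 4 arrays, adjusted p = 0.000257). EPB41, which anchors the red cell skeleton to its membrane, fell 1.83-fold (-0.87 ± 0.15, 4 of 4 arrays, adjusted p = 0.00036), and the red cell membrane proteins GYPC (-0.47 ± 0.10) and SLC4A1 (-0.33 ± 0.09) fell too. These were among the 4 of 8 erythroid markers that fell by either adjustment, in a list that did not pass its set test (adjusted p = 0.454). Genes best known from other tissues fell as well: MYH7, a muscle myosin, 4.58-fold (-2.19 ± 0.35, 4 of 4 arrays, adjusted p = 0.000229), VLDLR 2.37-fold (-1.24 ± 0.21), the adrenergic receptors ADRB1 (-1.20 ± 0.22) and ADRA1B (-0.94 ± 0.22), insulin, INS (-0.99 ± 0.23), B3GAT2 (-0.91 ± 0.19), the cone opsin OPN1LW (-0.91 ± 0.20) and the calcitonin receptor CALCR (-0.90 ± 0.17). The 7 other probes of MYH7, VLDLR, INS and B3GAT2 had a median log2 change of -0.05 and 0 were called. With the mean of a gene's probes MYH7 fell by 0.47 and VLDLR by 0.65 on the log2 scale, and with Feature Extraction signals MYH7 was at -3.62, VLDLR at -2.71 and SLC4A1 at -1.43. ADRA1B was at -0.38 without slide 2 (adjusted p = 0.286), and IL6ST at 0.19 with the mean of its probes (adjusted p = 0.088). GPX1 (-0.59 ± 0.12), the chemokine receptor CXCR3 (-0.74 ± 0.17) and the eosinophil and basophil receptors PTGDR2 (-0.46 ± 0.08) and CCR3 (-0.66 ± 0.22) fell, the last with its call lost in 27 of 49 alternative fits (adjusted p up to 0.471). Platelet markers rose: 3 of 7, or 4 adjusted over the list alone, with SELP 2.14-fold (1.1 ± 0.25, 4 of 4 arrays, adjusted p = 0.00411), GP1BA 2.1-fold (1.07 ± 0.27) and CLU 1.47-fold (0.56 ± 0.15). The list passed at adjusted p = 0.0109, against adjusted p = 0.738 with an estimated correlation and 0.0304 by fry. SELP stood at 2.06 on kibble 0/kibble 9 replicate 1, an array whose background exceeded its median signal, against 0.57 to 0.74 on the others. Without slide 1 it was at 0.90 and no longer passed in limma (adjusted p = 0.0855). PTGS1 (1.07 ± 0.28), SVIP (1.07 ± 0.32), the clotting inhibitor TFPI (1.06 ± 0.27), the nitric oxide receptor subunit GUCY1A1 (1.04 ± 0.20), PDE5A (0.70 ± 0.23), RLN2 (0.68 ± 0.19), MTPN (0.66 ± 0.13) and IL6ST (0.63 ± 0.21) rose. CPT1A rose by 0.37 ± 0.11, a call lost in 7 of 49 alternative fits and at 0.12 with median centring (adjusted p = 0.578), while UCP2 (-0.33 ± 0.10) and COX8A (-0.19 ± 0.05) fell. In all, 1311 genes rose and 2228 fell, a balance that depends on the scaling, with 2250 and 2343 for Feature Extraction signals and 1060 and 4569 for median centring. Without slide 1 the count was 1822 and without slide 2 832, and it was 2091 and 2248 without kibble 0/kibble 9 replicates 4 and 2.

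In the meat-fed dogs the change from week 0 to week 9 ran much the same way. LOC609402 fell 5.77-fold (log2 -2.53 ± 0.64, 4 of 4 arrays, adjusted p = 0.0151), MYH7 3.1-fold (-1.63 ± 0.35, 3 of 4 arrays, adjusted p = 0.00654) and EPB41 1.65-fold (-0.72 ± 0.15, 3 of 4 arrays, adjusted p = 0.0057). VLDLR (-0.97 ± 0.21), INS (-0.97 ± 0.23), ADRB1 (-0.94 ± 0.22), OPN1LW (-0.85 ± 0.20) and B3GAT2 (-0.83 ± 0.19) fell, while the other probes of MYH7, VLDLR, INS and B3GAT2 had a median of -0.01. With the mean of a gene's probes MYH7 was at -0.35 and VLDLR at -0.49, and with Feature Extraction signals they were at -2.36 and -1.69 and SLC4A1 at -1.04 (adjusted p = 0.127). IL18BP, which neutralises interleukin 18 (-1.18 ± 0.35), CD4 (-0.90 ± 0.27), GPX1 (-0.44 ± 0.12) and PTGDR2 (-0.35 ± 0.08) fell, with the CD4 call lost in 21 of 49 alternative fits (adjusted p up to 0.267) and the IL18BP call in 11 of 49 (adjusted p up to 0.274). Of 8 erythroid markers EPB41 and SLC4A1 (-0.36 ± 0.09) fell, or 3 adjusted over the list alone (set adjusted p = 0.202). MHC class II genes rose, 4 of 11 or 6 adjusted over the list alone: DLA-DQA1 (0.50 ± 0.11, 4 of 4 arrays, adjusted p = 0.00732), CTSS (0.53 ± 0.14), DLA-DMA (0.30 ± 0.09) and HLA-DRB1 (0.27 ± 0.08). Platelet markers rose, 2 of 7 or 4 adjusted over the list alone, SELP (1.05 ± 0.25) and GP1BA (0.93 ± 0.27). These lists passed at adjusted p = 0.00094 and 0.0283, with adjusted p = 0.738 for each under an estimated correlation and 0.06 and 0.0567 by fry. The platelet call was lost with the slide as a block (adjusted p = 0.0671), with scaling (adjusted p = 0.0566) and without slide 2 (adjusted p = 0.0683). GUCY1A1 2.32-fold (1.22 ± 0.20), selenoprotein P (SELENOP) 1.98-fold (0.99 ± 0.16, 4 of 4 arrays, adjusted p = 0.00226), SVIP (1.23 ± 0.32), PTGS1 (1.09 ± 0.28), the creatine-synthesis enzyme GATM (1.09 ± 0.33), TFPI (0.95 ± 0.27), DLC1 (0.86 ± 0.19) and TSHB (0.84 ± 0.25) rose, with the GATM call lost in 19 and the TSHB call in 16 of 49 alternative fits (adjusted p up to 0.361 and 0.333). In all, 968 genes rose and 1119 fell, a balance that moved to 68 and 329 without slide 2, 163 and 424 without slide 1, 1053 and 923 with Feature Extraction signals, and 74 and 40 on the arrays of this loop alone. The count was 268 without meat 9/meat 0 replicate 2 and 721 without replicate 3, 587 without slide 1, 397 without slide 2 and 114 with the arrays of this loop alone.

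**Figure D3:**
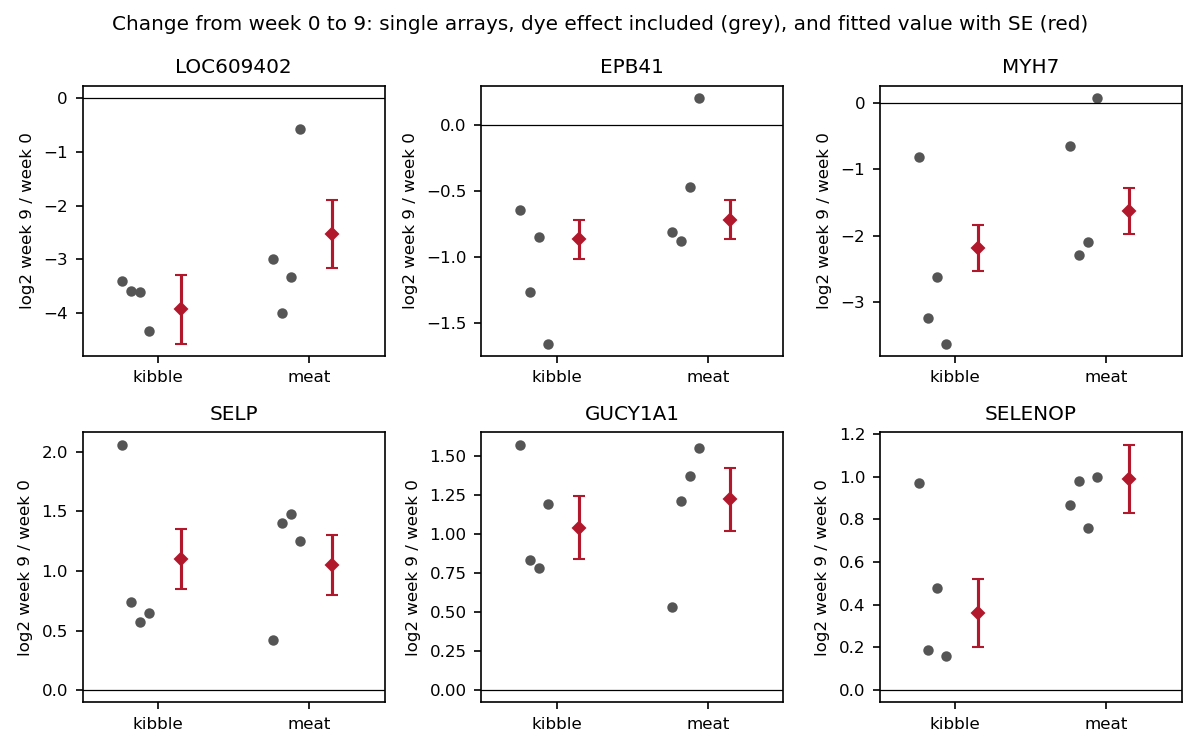
Log2 change from week 0 to week 9 on each diet for LOC609402, EPB41, MYH7, SELP, GUCY1A1 and SELENOP; grey points are the 4 arrays per diet, which still contain the dye effect, and red diamonds the fitted values with SE. LOC609402, EPB41 and MYH7 fell and SELP and GUCY1A1 rose on both diets, and SELENOP was at 0.99 ± 0.16 on meat and 0.36 ± 0.16 on kibble.

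The changes from week 0 to 9 on the 2 diets were alike across genes. The fitted changes correlated at 0.833, against 0.23 in simulated noise, with 441 genes called up on both diets, 923 down on both and 1 in opposite directions. The fits share arrays and the dye term, so the 2 changes are not independent. The interaction, which asks whether the change differed between diets, passed for 0 genes in limma (lowest adjusted p = 0.168, 2034 at an unadjusted p under 0.05). The 6 named genes with the smallest p were AP3M1 (log2 0.33 ± 0.08), NIP7 (0.28 ± 0.07), CLNS1A (0.23 ± 0.07), DNAJC25 (-0.30 ± 0.10), LIPF (-0.15 ± 0.05) and ZACN (-0.19 ± 0.06), with adjusted p between 0.293 and 0.496. DNAJC25 had the opposite sign with median centring (0.02), and ZACN without a dye term (0.11). On the time arrays the diets had opposite dye orders, so the interaction lies along the dye effect there. Only the fit with the diet arrays, on other slides, separates it from the dye. The list tests were not run without the dye term. MHC class II genes differed as a list, 10 of 11 positive in the sense of a larger rise on meat, with DLA-DMB at 0.40 ± 0.12 and DLA-DQB1 at 0.32 ± 0.13 (adjusted p = 0.00213, and adjusted p = 0.738 with an estimated correlation). At week 0 10 of 11 of these genes were negative in the meat group. Both results use the same week 0 samples, so a low start in that group would give this interaction. Ribosomal genes were 17 of 18 positive with RPL3 at 0.20 ± 0.07 (adjusted p = 0.043, and adjusted p = 0.786 with an estimated correlation), a call that scaling ended (adjusted p = 0.157). Adjusted over the list alone 1 MHC class II gene and 0 ribosomal genes passed. Fry gave adjusted p = 0.199 and 0.414.

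From week 3 to week 6 few genes passed in the kibble-fed dogs. PTGER4, a receptor for prostaglandin E2, rose 1.45-fold (log2 0.53 ± 0.10, 4 of 4 arrays, adjusted p = 0.0428) and was the 1 named gene called, with the call lost in 27 of 49 alternative fits (adjusted p up to 0.586). In all, 8 genes rose and 1 fell, against 4550 at an unadjusted p under 0.05, where chance gives 1298. The count was 393 with array weights, between 0 and 52 without single arrays, and 0 with the slide or the replicate number as a fixed block. The low count does not show an absence of change, and the 9 calls are not stable either. The next named genes did not pass: AP3M1 (0.24 ± 0.06), MAT2A (0.23 ± 0.06), RPS14 (-0.30 ± 0.07), CD8A (-0.77 ± 0.17) and BACE1 (-0.44 ± 0.10), with adjusted p between 0.0735 and 0.0926. The fitted value of RPS14 rests on the dye term, without which it was 0.02. Each kibble time array had the later week in Cy5, and the list tests that follow were not run without the dye term. The lists to the lower side were ribosomal genes (18 of 18 negative, RPL27 at -0.24 ± 0.07, adjusted p = 2.31e-07), cytotoxic markers (7 of 8 negative, CCL5 at -0.63 ± 0.23, adjusted p = 0.0283) and oxidative phosphorylation genes (5 of 5 negative, COX8A at -0.18 ± 0.05, adjusted p = 0.0437). Over all genes 0 of their members passed, and adjusted over the list alone 9, 2 and 2 did. The adjusted p = 0.738 for each with an estimated correlation, and fry gave 0.0354, 0.0939 and 0.0354. Median centring and the fit without slide 3 ended the oxidative phosphorylation call (adjusted p = 0.303 and 0.242), and scaling, the slide block and the fit without slide 4 ended the cytotoxic call (adjusted p = 0.0528, 0.1 and 0.263).

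In the meat-fed dogs PTGER4 rose by a like amount from week 3 to week 6 (1.43-fold, log2 0.51 ± 0.10, 4 of 4 arrays, adjusted p = 0.00614), a call that ended with the slide as a block (adjusted p = 0.0521), without slide 3 (adjusted p = 0.123) and without slide 4 (adjusted p = 0.084). The complement receptor C5AR1 rose 1.63-fold (0.70 ± 0.18, 4 of 4 arrays, adjusted p = 0.0358), ARG2 1.67-fold (0.74 ± 0.20, 4 of 4 arrays, adjusted p = 0.0468), and the survival genes MCL1 (0.49 ± 0.11) and BIRC3 (0.36 ± 0.10) rose. The ARG2 call was lost in 30 of 49 alternative fits (adjusted p up to 0.444) and the BIRC3 call in 34 of 49 (adjusted p up to 0.297). SELP fell 1.97-fold (-0.97 ± 0.25, 4 of 4 arrays, adjusted p = 0.0376), GUCY1A1 1.87-fold (-0.90 ± 0.20) and CCL4 1.55-fold (-0.63 ± 0.14). Of 7 platelet markers 1 fell, SELP, or 3 adjusted over the list alone, with GP1BA at -0.94 ± 0.27 (set adjusted p = 0.0109). Monocyte markers were 6 of 6 positive, with TLR4 at 0.45 ± 0.15 and 0 called over all genes or 2 adjusted over the list alone (set adjusted p = 0.01). Cytotoxic markers were 6 of 8 negative, with CD8A at -0.62 ± 0.17 and 0 called or 4 adjusted over the list alone (set adjusted p = 0.0402). For these 3 lists the adjusted p = 0.738 with an estimated correlation, and fry gave 0.0652, 0.0747 and 0.138. Each call was lost without slide 4 (adjusted p = 0.268, 0.125 and 0.167), and the cytotoxic call with either other normalisation (adjusted p = 0.124 and 0.0616). In all, 462 genes rose and 121 fell, against 2103 and 112 with median centring and 1475 and 977 with array weights. The count was 41 without slide 3, 43 without slide 4, 130 with the slide as a block, and 166 and 249 without meat 6/meat 3 replicates 4 and 2.

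The change from week 3 to 6 was tested for a difference between diets and passed for 0 genes in limma (lowest adjusted p = 0.481, 2523 at an unadjusted p under 0.05). Among the named genes with the smallest p were RPS10 (log2 0.19 ± 0.06), CLIC1 (0.31 ± 0.09), PSMD4 (0.20 ± 0.06), CRYGD (-0.29 ± 0.07) and MYH1 (-0.19 ± 0.05), each with adjusted p = 0.481. RPS10 had the opposite sign without a dye term (-0.12). On the time arrays the diets had opposite dye orders, so this difference lies along the dye effect there. Only the fit with the diet arrays, on other slides, separates it from the dye. The list tests were not run without the dye term. Lists passed for ribosomal genes (18 of 18 positive, mean log2 0.16, adjusted p = 8.34e-09), monocyte markers (6 of 6 positive, TLR4 at 0.40 ± 0.18, adjusted p = 0.0431) and platelet markers (5 of 7 negative, SELP at -0.77 ± 0.31, adjusted p = 0.0191). Adjusted over the list alone 1 ribosomal gene passed and 0 of the others, the adjusted p = 0.738 for each list with an estimated correlation, and fry gave 0.058, 0.24 and 0.25. Scaling (adjusted p = 0.0616) and the fit without slide 4 (adjusted p = 0.129) ended the monocyte call, and the slide block (adjusted p = 0.179) and the fit without slide 4 (adjusted p = 0.219) the platelet call.

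No array joins weeks 0 and 9 to weeks 3 and 6, so the changes from week 0 to weeks 3 and 6 come from the 2 channels read separately. In these values the week pair and the slide go together and cannot be told apart. In 25536 genes, MYH7 was lower than at week 0 at week 3 (log2 -1.71 ± 0.38 on kibble, -1.94 ± 0.38 on meat) and week 6 (-1.98 ± 0.38 and -2.23 ± 0.38). DEFB124, a beta-defensin, was higher at each, at 1.33 ± 0.29 and 1.63 ± 0.29 on kibble and 1.54 ± 0.29 and 1.17 ± 0.29 on meat. The MYH7 values rest on its brightest probe. From week 0 to 9 its other probes stood at -0.07 to 0.02 on kibble and -0.06 to 0 on meat, so they need not reflect the transcript. The oxidase DUOX1 was higher at week 6 on both diets (1.39 ± 0.29 on kibble, 1.14 ± 0.29 on meat) and at week 3 on meat (1.5 ± 0.30). On meat CCL5 was lower at week 6 (-1.48 ± 0.32), and on kibble EPB41 was lower at week 6 (-1.03 ± 0.16). On kibble 3769 genes were called at week 3 and 4261 at week 6, and on meat 4597 and 3541.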

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

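Of the tests in this part, the week 0 comparison, the dye comparison, the other probes and the values of CAMP and MS4A2 beside a platelet index were chosen after the result was seen. For the platelet and red cell covariates, the limit set beforehand for an explanation was under 10 percent of genes kept, and both values met it. A second condition, that the median size falls under 50 percent of what it was, was added after the values were seen because the covariates widened the SEs, and neither met that. The lists, and the settings not named as later additions, were fixed before the data were examined, and the other tests before their own result was seen.

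Single arrays stood far from the other 3 of their kind for 5 named genes. PLA2G15 stood at log2 1.09 on kibble 6/meat 6 replicate 1 against 0.18 to 0.33 on the others (gap over range 0.83). PRF1 stood at -0.21 on meat 6/kibble 6 replicate 1 against -0.86 to -0.75 (0.83), and ATP2B1 at -0.87 on meat 9/kibble 9 replicate 1 against -0.5 to -0.43 (0.854). SELP had 2.06 on kibble 0/kibble 9 replicate 1 against 0.57 to 0.74 (0.887), and TFPI -0.01 on meat 9/meat 0 replicate 1 against 1.04 to 1.18 (0.88). These are 5 of 111 groups of 4 arrays, where chance gives 5.6, about 1 in 20.

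Array measures stood apart more often, in 7 of 28 groups where chance gives 1.4. Kibble 0/kibble 9 replicate 1 had a background of 160.5 in Cy3 against 19 to 21 (0.986) and 306 in Cy5 against 53 to 58 (0.98), with 38 faulty spots against 8 to 11 (0.9). Meat 9/meat 0 replicate 1 had 42703 probes above background in Cy3 against 26506 to 26653 (0.991), 43411 in Cy5 against 30006 to 31039 (0.923) and 437 faulty spots against 11 to 13 (0.995). Both are on slide 1, and the outlying values of SELP and TFPI lay on these arrays. The SD of the log ratios on kibble 3/kibble 6 replicate 2 was 0.403 against 0.18 to 0.202 (0.901).

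List differences between the diets' changes passed camera in 9 cases. From week 0 to 9 these were MHC class II (adjusted p = 0.00213) and ribosomal genes (0.043), and from week 3 to 6 ribosomal genes (8.34e-09), monocyte (0.0431) and platelet markers (0.0191). For weeks 3, 6 and 9 against week 0 they were interferon-stimulated genes (0.00161), ribosomal genes (6.84e-09), cytotoxic (0.0214) and dendritic cell markers (0.04). With an estimated correlation the adjusted p was 0.786 for the ribosomal list from week 0 to 9 and 0.738 for each other. No list test was run without the dye term, though the time arrays of the diets had opposite dye orders.

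The diet difference over weeks 3, 6 and 9 may in part have been present before feeding. For 500 genes picked on the week 3 diet arrays, the mean difference on the week 0 arrays was 0.45 of that on the week 6 arrays (0.149 against 0.331), with single week 0 arrays between 0.00292 and 0.577, so the share cannot be told from 3 arrays. Platelets carried over with the mononuclear cells are another candidate explanation. With an index of the 7 platelet markers as a covariate 3.88% of the called genes outside the list stayed called (150 of 3865), but the median size went only from 0.225 to 0.164 while the median SE rose from 0.0559 to 0.0845, so the limit set beforehand was met, partly through wider errors, and platelets and diet cannot be told apart for most genes. For MS4A2 (-1.33 ± 0.18, adjusted p = 0.000253) and CAMP (-2.32 ± 0.47, adjusted p = 0.0138) the difference remained beside the index, which argues against platelets as their source. Of the 8 genes looked at this way the other 6 lost their calls: AK1 went from -1.04 to -0.32, CCL5 from -0.92 to -0.55, RPS27A from 0.31 to 0.17, CYBB from -0.69 to -0.51, LTF from -0.77 to -0.65 and CD163 from -0.60 to -0.46. At week 0 MS4A2 already stood at log2 -1.17 ± 0.18, against -1.17 ± 0.11 over weeks 3, 6 and 9. That argues against the diet as the source of the MS4A2 difference, though from 3 week 0 diet arrays on a slide of their own. For the pattern at large the diet itself and differences between the dogs stay open.

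The change from week 0 to 9 shared by both diets is not accounted for by dye bias, since the dye orders were opposite and the uncorrected ratios still correlated across genes at 0.626 (0.65 on slide 1 and 0.381 on slide 2). Red cell RNA carried over in differing amounts is a candidate explanation, since red cell membrane genes fell. The measure used for it, LOC609402, has no known function here, and its link to red cells rests only on its place near a globin gene in the reference table. With the log ratio of LOC609402 as a covariate 2.05% of the shared genes stayed called in both diets (28 of 1363), but the median size fell only from 0.454 to 0.278 on kibble and from 0.395 to 0.3 on meat, while the median SE rose from 0.0993 to 0.147 and 0.119, so here too the limit set beforehand was met, partly through wider errors, and red cell RNA cannot be told apart from a change with time. Season, age and handling on the day are confounded with the week and were not tested.

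The fall of 7 genes, among them MYH7, VLDLR, ADRB1, INS, B3GAT2 and OPN1LW, is unlikely to be a change in the transcripts of MYH7, VLDLR, INS and B3GAT2 that all their probes read, since 7 other probes of these 4 genes had a median change of -0.05 on kibble. The 7 genes may share the signal of 1 abundant RNA. Their residuals correlated with each other at a mean of 0.873 and with LOC609402 at a median of 0.69 (0.36 to 0.71) over the arrays, against a median of 0.0081 and a 95th percentile of 0.48 for all named genes, which leaves the source open.

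Reassigning the array labels 100 times tests the arrangement of the arrays and not of the dogs, since the same dogs recur on several arrays. All labels were shuffled at once, so real differences of the other comparisons entered the spread, and slides and shared dogs were not kept together. The counts therefore cannot exclude chance for any one comparison. For the diet difference at week 3 (1580 genes, highest other 2606) 2 of 100 assignments, the real one included, were as large. At week 6 (1617, 2) and over weeks 3, 6 and 9 (3870, 708) it was 1 of 100, the real one. The same held for week 0 to 9 on kibble (3539, 58) and meat (2087, 536) and for week 3 to 6 on kibble (9, 0) and meat (583, 10). The 9 calls on kibble ended with the slide or the replicate number as a fixed block. For week 0 (81, 724) and week 9 (151, 676) 2 of 100 were as large. There, as at week 3, an assignment called more genes than the real one, and the reason was not tested. The interactions were counted at an unadjusted p under 0.05. As large were 13 of 100 at week 9 (2034, 5311), 9 of 100 against week 0 (2346, 6064) and 4 of 100 at week 6 (2523, 3857). For the total number of list tests passing (37, 35) 1 of 100 was as large. The median of the other assignments was 18 and 98 of them passed at least 1, so many single list calls are of a kind that reassigned labels also give. For the changes between the loops (1578 among every 10th gene, 204, 1 of 40) the reassigned labels mix slides that the real ones keep together, so a slide effect alone would give the same outcome.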

How the results depend on the processing

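The dye term per scan session, the fits without single slides or without the first 2 arrays of slide 1, and the list tests by setting were chosen after the results were seen. Of 3695 values of named genes under other settings 3036 kept direction and side of the threshold, 650 no longer passed, 5 newly passed and 4 turned direction. With 1 array left out it was 5582, 534, 4 and 0 of 6120. Of the called genes that the naming rule picked, 19 of 49 over weeks 3, 6 and 9 stayed called in each setting run, 9 of 35 on kibble from week 0 to 9 and 1 of 29 on meat. It was 0 of 4, 22, 24 and 10 for the diet difference at weeks 0, 3, 6 and 9 and 0 of 1 and 7 for week 3 to 6 on kibble and meat. The size of single genes moved too, as for MYH7 on kibble (-3.62 to -0.47 against -2.19) and VLDLR (-2.71 to -0.65 against -1.24). Calls close to the threshold were lost in many fits, as for CYP3A12 (20 of 48) and TXNRD1 (16 of 48) at week 3, CCR9 and FASLG (19 of 48 each) at week 6, HMOX1 (18 of 47) over weeks 3, 6 and 9, PDE5A (18 of 49) and IL6ST (23 of 49) from week 0 to 9 on kibble and SELP (19 of 49) from week 3 to 6 on meat. The cause of a moved value was not tested, except where fewer arrays or genes enter the fit.

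The counts of called genes that moved by over 1.5 times are set against 81, 1580, 1617 and 151 for the diet difference at weeks 0, 3, 6 and 9, 3870 for its mean, 3539 and 2087 for week 0 to 9 on kibble and meat, and 9 and 583 for week 3 to 6. Without background correction week 3 to 6 on kibble gave 31. Feature Extraction signals gave 20 at week 0, 1034 at week 3, 14 on kibble and 364 on meat from week 3 to 6, and 1 for the interaction of weeks 3 and 6. The deposited values gave 47 at week 0 and 36 for week 3 to 6 on kibble. Median centring gave 36, 127, 358 and 10 at weeks 0, 3, 6 and 9, 1080 for the mean, 5629 and 764 for week 0 to 9 on kibble and meat, 1 and 2215 for week 3 to 6, and turned DNAJC25 in the week 9 interaction to 0.02. It also shifted the share of higher genes from 37.8 to 5.51 percent at week 3 and from 37 to 18.8 percent for week 0 to 9 on kibble. Scaling gave 28 at week 0, 2525 at week 6, 63 at week 9, 1243 for week 0 to 9 on meat, and 23 and 318 for week 3 to 6 on kibble and meat. The filter of 30 channels gave 22 for week 3 to 6 on kibble. Without a dye term week 0 gave 48 and week 3 to 6 gave 25 on kibble and 318 on meat, and RPS14 (0.02, week 3 to 6 on kibble), ZACN (0.11, week 9 interaction) and RPS10 (-0.12, week 6 interaction) turned direction.

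With the slide as a fixed block the counts were 15, 418, 463 and 69 at weeks 0, 3, 6 and 9, 744 for week 0 to 9 on meat, and 0 and 130 for week 3 to 6 on kibble and meat. As a random block it gave 17 for week 3 to 6 on kibble. The replicate block gave 44 at week 0, 98 at week 9 and 0 for week 3 to 6 on kibble, and 4 of 24 pairs of replicates correlated best with their own number, 3 of them between kibble 0/kibble 9 and kibble 3/kibble 6 (0.38, 0.41 and 0.42) while others reached -0.8, so whether the numbers pair the samples stays open. Trend and robust moderation gave 3 for week 3 to 6 on kibble. Array weights gave 3151 at week 6, 3410 for week 0 to 9 on meat, 393 and 2452 for week 3 to 6 on kibble and meat, and 2 for the week 6 interaction. The arrays of the loop alone gave 38 at week 0, 51 at week 9, 114 for week 0 to 9 on meat, and 0 and 277 for week 3 to 6, and cannot give the mean or its difference from week 0. The arrays of the 2 groups alone gave 0, 0, 1 and 0 at weeks 0, 3, 6 and 9 in limma and 2388 for the mean, with fewer arrays to estimate the spread. A dye term per scan session gave 30 at week 0, 573 at week 3, 94 at week 9, 1384 for week 0 to 9 on meat, and 0 and 349 for week 3 to 6. Without the first 2 arrays of slide 1 week 3 to 6 on kibble gave 30. Without slide 1 week 0 to 9 gave 1822 on kibble and 587 on meat, and without slide 2 832 and 397. Without slide 3 week 3 to 6 gave 0 and 41, and without slide 4 1 and 43.

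Of the 37 list tests that passed, an estimated correlation left 0 and fry 12, and fry passed 23 of all 216. Of the 37, 35 were kept without background correction, 33 with Feature Extraction signals, 32 with the replicate block, 29 with the slide block, 37 without the first 2 arrays of slide 1, 31 with median centring and 24 with scaling. In these settings no list turned direction.

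Leaving out each array gave 23 to 218 genes at week 0, with 46 without kibble 0/kibble 9 replicate 2, 45 without meat 9/meat 0 replicate 2, 51 and 218 without meat 0/kibble 0 replicates 1 and 2, 23 without kibble 0/meat 0 replicate 1 and 50 without meat 9/kibble 9 replicate 2. At week 3 it gave 215 to 2070 (587 without kibble 3/meat 3 replicate 1, 215 without meat 3/kibble 3 replicate 2), at week 6 138 to 2254 (138 and 950 without kibble 6/meat 6 replicates 1 and 2) and at week 9 42 to 195 (53 without meat 9/kibble 9 replicate 1, 42 without kibble 9/meat 9 replicate 2). The mean ranged from 2795 to 4255. Week 0 to 9 gave 2091 to 3799 on kibble (2248 and 2091 without kibble 0/kibble 9 replicates 2 and 4) and 268 to 2660 on meat (268 and 721 without meat 9/meat 0 replicates 2 and 3). Week 3 to 6 on meat gave 166 to 708 (249 and 166 without meat 6/meat 3 replicates 2 and 4). On kibble it gave 0 to 52, where 22 arrays moved the count. It was 27 and 3 without meat 9/meat 0 replicates 1 and 4, 17 and 0 without kibble 0/kibble 9 replicates 3 and 4, 0, 0, 1 and 0 without kibble 3/kibble 6 replicates 1 to 4, and 52, 4, 0 and 4 without meat 6/meat 3 replicates 1 to 4. It was 43 and 14 without meat 0/kibble 0 replicates 1 and 2, 0 without either meat 3/kibble 3 array, 0 and 4 without kibble 6/meat 6 replicates 1 and 2, 15 without meat 6/kibble 6 replicate 2, 0 without meat 9/kibble 9 replicate 2, and 5 and 0 without kibble 9/meat 9 replicates 1 and 2. The week 9 interaction gave 0 to 2 (2 without meat 9/kibble 9 replicate 2), the week 6 interaction 0 to 0, and the difference from week 0 gave 0 to 237 (1 without kibble 0/kibble 9 replicate 4, 237 without meat 0/kibble 0 replicate 1).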

Other observations

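Over weeks 3, 6 and 9 GYPC, a red cell membrane protein, was higher in meat-fed dogs (log2 0.19 ± 0.06, adjusted p = 0.0478, a call lost in 26 of 47 alternative fits with adjusted p up to 0.223), and of 8 erythroid markers 1 was higher and 1 lower by either adjustment (list adjusted p = 0.693). CD1A8, the 1 dendritic cell marker of 5 called, was higher (0.18 ± 0.06, adjusted p = 0.0236). FOSB, an immediate early transcription factor, fell from week 0 to 9 by similar amounts on kibble (-0.26 ± 0.08, adjusted p = 0.0263) and meat (-0.27 ± 0.08, adjusted p = 0.0275).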
